A study of Rattus norvegicus with 20 samples.

How the data were processed

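The study measured mRNA, genomic DNA and chromatin immunoprecipitates (ChIP) from the left ventricle of a normal and a failed heart of Dahl rats, on 20 Affymetrix Rat Genome 230 2.0 arrays. Each heart had 10 arrays: mRNA, genomic DNA taken before immunoprecipitation (pre-IP), and ChIP for 8 histone marks. The marks were acetylated histone H3 (H3ac), acetylated histone H4 (H4ac), and the lysine methylations K4me2, K4me3, K9me2, K9me3, K20me3 and K27me2, for which the labels do not name the histone. There was 1 array per assay and heart. Per the labels, total RNA was turned into biotin-labelled cDNA, while fragmented DNA was amplified by T7 transcription and then labelled. The arrays are expression arrays, so a ChIP value describes DNA under probes designed for transcripts, not a promoter. Per the study's design, each experiment used a single left ventricle specimen; whether the 10 assays of a heart shared that specimen is not given in the sources used here. The label of the normal H4ac array names acetylated H4 in its title, description and protocol and pre-IP genomic DNA as its source; it was used as H4ac.

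The deposited values are intensity, on a linear scale, with 1 value per probe set and array for 31099 probe sets, of which 57 are controls. Every array had a mean of about the same size after removal of 2% of the values at each end, between 500.03 and 500.17, as global scaling of Affymetrix arrays gives. The tool that summarised and scaled the values is not given in the sources used here. Array medians ran from 189 on the failed mRNA array to 415 on the normal K9me2 array. Arrays give no counts, so the number of arrays limits the precision: with 1 array per group no p-value, error or replicate check was possible.

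Each array was rescaled to a median of 100, values under a floor of 10 were set to 10, and log2 was taken. The floor touched between 2.04% and 11.0% of the probe sets of an array. Of the probe sets, 20832 belonged to exactly 1 gene in the annotation used, 436 to several and 9780 were not listed. The last 2 kinds were left out. A few control probe sets are among those listed and were left out as well, and the 9780 do not include controls. Gene identifiers of 20764 probe sets were matched to the current gene table, which renamed 0 of them. A gene was represented by the probe set with the highest mean mRNA level, which gave 14217 genes, 4525 of them with 2 or more probe sets. Enrichment of a mark was log2 ChIP minus log2 pre-IP of the same heart. A difference was always failed minus normal. Differences were counted when they reached 1 in size on the log2 scale (2-fold), among genes whose mean level over the arrays compared was at or above the median over all probe sets.

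The comparisons were the mRNA difference, the pre-IP difference as background, the enrichment difference of each mark, Spearman's rho across genes of each mark's enrichment with the mRNA level in each heart, rho of mark differences with mRNA differences, mark differences at genes with a 2-fold mRNA difference, and rho between marks for 28 pairs. Genes are not independent replicates, so these rho values carry no p-value. The correlation between 2 probe sets of the same gene was used as a measure of how much of a value recurred at another probe set. These were the first 2 in identifier order that passed the level filter. Probe positions were not used, so the 2 may lie close together.

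Fixed before the data were examined were 22 gene lists. They were natriuretic peptide and hypertrophy, adult sarcomere, calcium handling, extracellular matrix, fatty acid oxidation, respiratory chain, glycolysis, potassium and sodium channel, neurohumoral, stress response, histone modifying enzyme, ribosomal protein, liver and brain, and developmental transcription factor genes, and markers of fibroblasts, endothelium, smooth muscle, macrophages and leukocytes, red blood cells, adipocytes, atrial muscle and skeletal muscle. The median of a list was placed among the medians of 10000 random lists of the same size, matched in 20 bins of level. A list of fewer than 5 measured genes got no percentile. The 95% range of these random medians is called the matched range. The percentile describes these arrays and is not a test between animals.

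Named genes followed a rule also fixed before the data were examined. For mRNA it took the 10 largest differences each way, and Nppa, Nppb, Acta1, Myh7, Myh6, Atp2a2, Ankrd1, Ccn2, Postn, Col1a1, Col3a1, Timp1, Cpt1b and Pdk4 whatever their values. For each mark it took the 3 largest differences each way and the 3 highest enrichments. The values of each mark at 8 of the preset genes were also taken. For pre-IP it took the 2 largest differences each way, and inside a list up to 4 members. Predicted genes without a proper symbol were passed over for naming. Other genes that are named were chosen after their values were seen, and this is said where it applies.

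The counting was tested on simulated data: the normal mRNA array was multiplied by noise drawn from the differences between the pre-IP arrays, and 200 genes were changed by a known amount. With noise drawn from probe sets of the same rank of level, 20.0% of genes changed 1.5-fold, 50.0% of those changed 2-fold, 86.0% of those changed 3-fold and 96.0% of those changed 4-fold were counted, beside 7.54% of unchanged genes. With noise drawn whatever the level, the shares were 28.0%, 60.0%, 82.0% and 92.0%, beside 16.6% of unchanged genes. The noise matched on level was added after the unmatched kind had been run. Of 200 simulated unchanged lists of 20 genes 4.00% lay outside the matched range, and of as many lists shifted by 0.5 on the log2 scale 91.0% did.

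Also chosen before the data were examined were these other settings: values as deposited without rescaling, quantile normalization, no floor, a floor of 50, no level filter, the mean of a gene's probe sets, no probe sets whose identifier ends in _x_at or _s_at, and ChIP without pre-IP. Enrichment over the mean of both pre-IP arrays, gene lists on the values as deposited, and zinc finger genes under other scalings and a floor of 50, were added after the data were seen. A table of rat genes was used for symbols, named pseudogenes and the order of genes along chromosomes; probe positions were not used here. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. While the work was under way, a rule that let an old synonym override a current symbol was found and removed, which took 1 gene from each of 2 lists.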

Results

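Left ventricle of a normal and a failed heart was compared in Dahl rats, lines bred for their blood pressure response to dietary salt. The labels describe the failed heart as congestive heart failure, name a high-sodium diet for its mRNA sample only, and give an age of 19 weeks for all samples except the normal H4ac sample, whose label gives none. Each heart was measured on 10 arrays: mRNA, pre-IP genomic DNA, and ChIP for H3ac, H4ac, K4me2, K4me3, K9me2, K9me3, K20me3 and K27me2. There was 1 array for each assay in each heart, so no value below has a replicate error, and differences are those between 2 arrays. The labels call the mRNA left ventricular myocytes, and genes of other cell types were measured on the same arrays. All differences are failed minus normal on the log2 scale unless stated otherwise.

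The mRNA comparison asked which genes differed between the failed and the normal heart. Genes of the extracellular matrix, of cardiac hypertrophy and of macrophages had more mRNA in the failed heart, and smooth muscle genes had less. Postn, a matricellular protein of injured heart, had the largest difference at 4.78, which is 27.4-fold. Next came Ltbp2, a protein that binds matrix microfibrils, at 4.72, Ankrd23, a muscle ankyrin repeat protein, at 4.64, Reg3b, a secreted lectin, at 4.42, and Nppa, which encodes atrial natriuretic peptide, at 4.30. Apobec2 followed at 3.69, Ecrg4 at 3.37, Egr2 at 3.36, Srxn1 at 3.32 and Maoa, a monoamine oxidase, at 3.30. A second probe set of Egr2 went the other way at -1.34. At the other end were Lrrn2 at -2.69, Plxnd1, a semaphorin receptor, at -2.51, Tmem82 at -2.43, Ros1 at -2.42, Sox10, a neural crest transcription factor, at -2.38, Btnl9 at -2.29, Ky at -2.27, Sned1 at -2.25, Tbx19 at -2.24 and C5h1orf127 at -2.24.

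The preset heart failure genes were mostly higher in the failed heart. Nppb, which encodes brain natriuretic peptide, differed by 2.46, the skeletal actin gene Acta1 by 1.92, the stress gene Ankrd1 by 2.14 and the connective tissue growth factor gene Ccn2 by 3.04. Myh7, the slow myosin heavy chain, was higher by 1.61 and Myh6, the fast one, differed by -1.03, with -3.32 at its second probe set. The collagens Col1a1 and Col3a1 differed by 0.99 and 1.44 and the protease inhibitor Timp1 by 1.07. Less than 2-fold were the calcium pump gene Atp2a2 at 0.74, whose 5 probe sets ran from -0.95 to 0.81, Cpt1b, which carries fatty acids into mitochondria, at -0.69, and the kinase gene Pdk4 at 0.41.

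Of 9317 genes compared, 1104 were at least 2-fold higher and 293 at least 2-fold lower in the failed heart, 15% in all. The balance between the directions depended on the scaling. With values as deposited 568 were higher and 639 lower, and with quantile normalization 585 were higher and 534 lower. The median of all probe sets differed by -0.27 as deposited, and rescaling sets it to 0. Of the 1397 genes counted, 861 were also counted as deposited and 877 after quantile normalization. The pre-IP arrays, made from genomic DNA per the labels, gave 7.46% of genes past 2-fold. The simulated unchanged genes gave 7.54% with noise matched on level. With noise drawn whatever the level, which puts noise of dim probe sets on brighter ones, they gave 16.6%. The 15% for mRNA lay above the first 2 shares and below the last, so whether the count exceeds noise depends on the noise taken. All simulated noise was drawn from the pre-IP differences, so the 7.54% follows the 7.46% and is not a separate reference. Noise between mRNA arrays of the same heart could not be measured. Differences of 2 probe sets of the same gene correlated with Pearson's r of 0.44 over 1833 genes for mRNA and 0.13 over 1846 genes for pre-IP DNA.

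Among muscle lists, natriuretic peptide and hypertrophy genes had the highest median, 1.60, above all 10000 matched lists. Of 11 members passing the level filter 9 were at least 2-fold higher and 0 lower; Csrp3, a stretch-associated muscle protein, differed by 2.54 and Myl4, an atrial light chain, by -0.06. Adult sarcomere genes had a median of 0.70, at percentile 71.4, with 7 of 15 higher and 1 lower. Actn2 at 1.78 and Myoz2 at 1.51 were the highest and Myh6 and Tnni3, at -0.38, the lowest. With quantile normalization this list stood at percentile 99.4. Calcium handling genes had a median of 0.29, at percentile 15.7, which was -0.26 with quantile normalization. In that list 1 of 13 was higher, the sodium-calcium exchanger gene Slc8a1 at 1.93, and the others lay between Casq2 at 0.83 and Cacna1c at -0.63. Potassium and sodium channel genes had a median of 0.01, at percentile 27.8, and of -0.22 as deposited and -0.17 with quantile normalization. Of 10, Kcnj11 was higher at 2.15, with another probe set at -1.17, and Kcnd3 at -1.54 and Kcna5 at -1.44 were lower. Neurohumoral genes had a median of 0.06, at percentile 44.2, and of -0.20 as deposited, with Ace, the angiotensin converting enzyme gene, at 1.48 and Npr2 at -1.25 past 2-fold among 6.

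Matrix and cell type markers were among the lists farthest from their matched ranges. Extracellular matrix genes had a median of 1.12, above all matched lists, with 17 of 29 members at least 2-fold higher and 0 lower. Besides Postn and Ccn2, Thbs4 differed by 3.23, while the elastin gene Eln differed by -0.47 and Fmod by -0.32. Macrophage and leukocyte markers had a median of 0.96, above all matched lists, with 7 of 15 higher, among them Lyz2, a lysozyme, at 2.53 and the complement gene C1qa at 1.74. The pan-leukocyte gene Ptprc differed by -0.22, and by 1.10 at its other probe set. Fibroblast markers had a median of 0.94, at percentile 98.0, with 3 of 9 higher, of which Col1a2 at 1.63 and Col3a1 also belong to the matrix list. Smooth muscle markers had a median of -1.13, below all matched lists, with 6 of 7 at least 2-fold lower, among them Cnn1 at -1.50 and Tagln at -1.29. Endothelial markers had a median of -0.47, at percentile 0.040, but of 0.14, at percentile 19.1, when a gene's probe sets were averaged. Of 9 endothelial markers Vwf was higher at 1.16, and Emcn at -0.72 was the lowest. Adipocyte markers had a median of -0.19, at percentile 7.96, with 0 of 4 past 2-fold, and lay just outside the matched range, at percentile 2.42, with quantile normalization, where the median was -0.43, and as deposited, where it was -0.45. Skeletal muscle markers had a median of -0.45, at percentile 8.11, or 1.88 with the floor at 50, with Myh1 at -0.45. The red blood cell genes differed by 2.13 for Hbb, 0.89 for Alas2, 0.62 for Slc4a1, whose other probe set gave -2.87, and -2.48 for Epb42, which lay below the level filter. The atrial genes Myl7 and Sln, also below that filter, differed by 2.66 and -1.53.

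Genes of energy supply formed 3 lists, which were not tested against each other. Glycolysis genes had a median of 0.91, at percentile 99.7, with 6 of 14 higher and 0 lower. The median was 0.64 as deposited and 0.52 with quantile normalization, still outside the matched range. Member counts past 2-fold are for the rescaled arrays only, and the shift of -0.27 as deposited would take members just above 2-fold out of them. Pgk1 at 1.48, with another probe set at -0.68, and the lactate dehydrogenase gene Ldha at 1.39 were the highest, and the glucose transporter gene Slc2a4 the lowest at -0.52. Respiratory chain genes had a median of 0.84, at percentile 98.7, or 92.3 when a gene's probe sets were averaged. In that list 12 of 27 were higher, led by the ATP synthase gene Atp5f1a at 2.14 and Cox6a2 at 1.86, and Cox8b was the lowest at -0.30. Fatty acid oxidation genes had a median of 0.24, at percentile 23.6, which was -0.06 with quantile normalization and -0.02 as deposited. Of 24, Cpt2 at 2.45, Acadl at 1.69 and 2 more were higher, and Cpt1b and Cpt1a, at -0.66, were the lowest. Ribosomal protein genes had a median of 0.88, at percentile 95, with 4 of 17 higher, among them Rps3 at 1.27. Stress response genes had a median of 0.49, at percentile 92.2, with 5 of 15 higher, among them Gadd45b at 2.21 and Junb at 1.63. Histone modifying enzyme genes had a median of 0.06, at percentile 14.8, and of -0.21 as deposited and -0.11 with quantile normalization. In this list 0 of 29 were higher and 2 lower, Kmt5c, a methyltransferase for lysine 20 of histone H4, at -1.71 and Dot1l, one for lysine 79 of histone H3, at -1.14. Liver and brain genes and developmental transcription factor genes, chosen as lists silent in heart, had medians of 0.00 and 0.00, at percentiles 50.1 and 54.2. Not all members were silent: 7 of 31 and 2 of 29 passed the level filter. Of these, Cyp2e1 at -1.95 and Sox10 at -2.38 were at least 2-fold lower and 0 were higher. The liver and brain median was -0.14 as deposited. When probe sets were averaged it was -0.32, at percentile 2.09 and so outside the matched range. The control probe sets for RNA integrity moved apart: the ratio of 3′ to 5′ signal was 11.3 in the normal and 22.6 in the failed heart for GAPDH, and 18.2 and 12.4 for beta-actin. In both hearts 3′ signal was thus many times 5′ signal. What this does to the mRNA differences, and to probe sets of a gene that differ, was not tested.

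**Figure D1:**
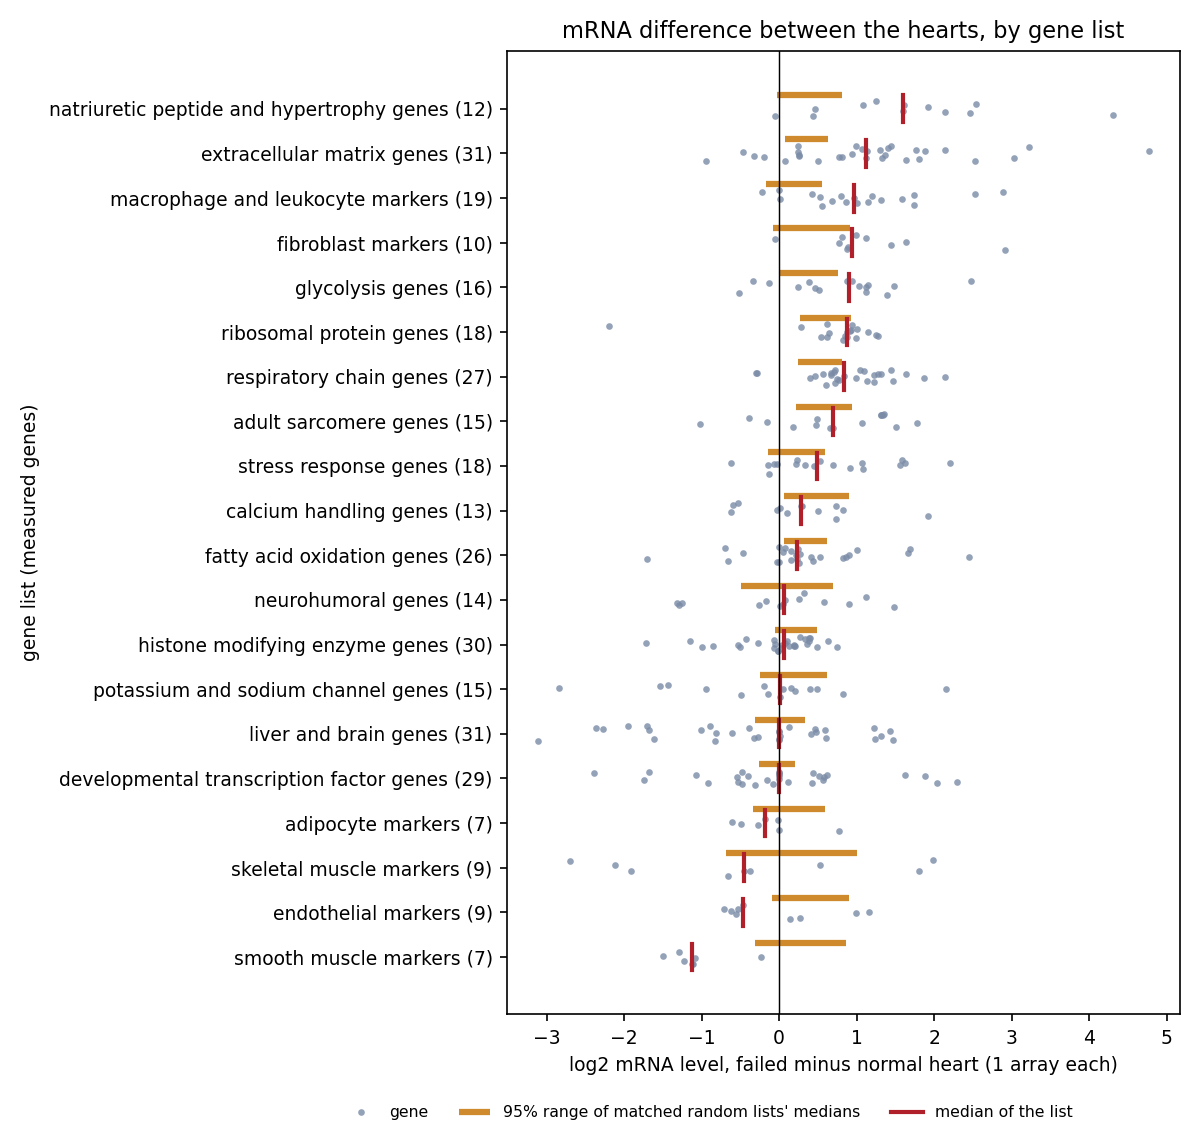
Each point is a gene, placed by its log2 mRNA level in the failed minus the normal heart (1 array each), for the 20 lists with at least 5 measured genes; red lines are list medians and orange bars the 95% range of the medians of matched random lists. Hypertrophy (1.60) and extracellular matrix genes (1.12) lie above that range and smooth muscle markers (-1.13) below it; the endothelial median of -0.47 turns to 0.14 when probe sets are averaged, and the medians of calcium handling, fatty acid oxidation, channel, neurohumoral, histone modifying enzyme and liver and brain genes turn negative under at least 1 other scaling.

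Within each heart, several gene lists stood apart in their marks, on the same side in both hearts. Stress response genes, many of them immediate early genes, were enriched in H3ac, with medians of 0.98 in the normal and 0.91 in the failed heart, and in K4me2, with 1.17 and 1.38. These sizes depended on the scaling: with quantile normalization they were 0.75 and 0.28 for H3ac and 0.60 and 0.56 for K4me2, and as deposited 0.63 and 0.52 for H3ac and 0.72 and 0.70 for K4me2, still outside the matched range. In each of these marks 16 of 18 members lay above 0 in both hearts; Ier3 had H3ac enrichments of 2.80 and 1.53 and K4me2 enrichments of 3.11 and 2.12. Developmental transcription factor genes had been chosen as silent in heart, and 2 of 29 passed the mRNA level filter. They were low in H4ac, with medians of -0.93 and -1.25, and in H3ac, with -0.62 and -0.52. In K9me3 they were high, with 1.10 and 0.76. For K9me3, 22 of 29 lay above 0 in both hearts, and Sox2 had 1.77 and 1.84; for H4ac, 20 of 29 lay below 0, and Pdx1 had -2.63 and -3.03; for H3ac, 15 of 29 lay below 0. With the floor at 50 the medians of these genes shrank to -0.35 and -0.57 for H4ac and to -0.17 and -0.17 for H3ac, and as deposited those for H3ac were -1.04 and -0.91, outside the matched range in each case. The same list was low in K27me2, with -0.60 and -0.97 and 17 of 29 below 0 in both hearts, but with the floor at 50 the medians were 0.00, at percentile 40.9, and -0.47. Liver and brain genes were low in H4ac, with -1.01 and -0.92 and 22 of 31 below 0 in both hearts, and with -0.29 and -0.30 with the floor at 50. Adult sarcomere genes were low in K20me3, with -1.13 and -0.92, and in K27me2, with -1.07 and -0.99. For each of these marks 12 of 15 lay below 0 in both hearts; Tcap, a Z-disc protein, had K27me2 enrichments of -2.62 and -1.22. Respiratory chain genes were low in K27me2, with -0.82 and -0.76 and 24 of 27 below 0 in both hearts. Also outside their matched ranges were fatty acid oxidation genes, with K9me3 medians of 0.30 and 0.30 and only 11 of 26 above 0 in both hearts, and neurohumoral genes, with K9me2 medians of 0.61 and 0.67 and 8 of 14 above 0. For the first the failed heart's median was 0.06, at percentile 83.3, when probe sets were averaged, and for the second the normal heart's lay at percentile 97.1 with quantile normalization, both inside the matched range. The member genes named in this paragraph were chosen after their values were seen.

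These 12 combinations of list and mark, of 160, lay outside the matched range on the same side in both hearts, where 0.20 would be expected if the hearts were independent and lists were random draws. On opposite sides there were 0. The arrays of both hearts share probes, so features of a probe set that raise or lower its signal can recur in both.

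**Figure D2:**
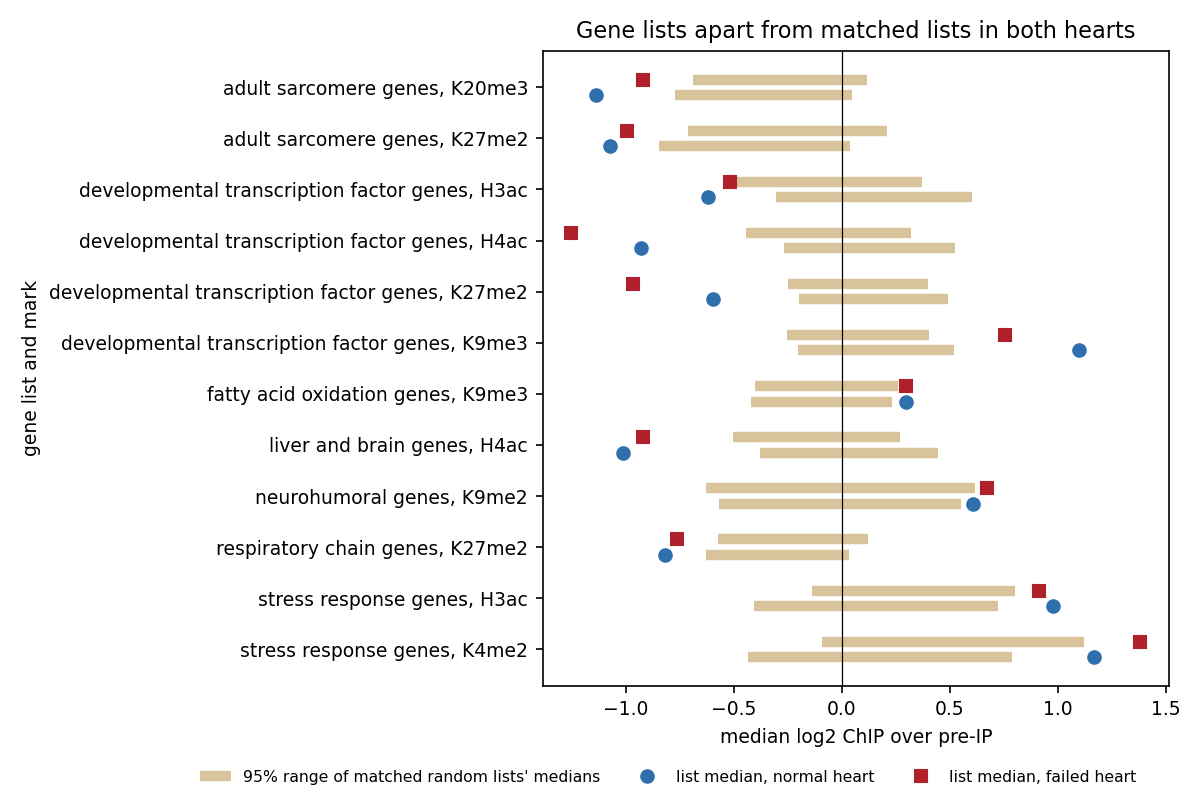
Median log2 ChIP over pre-IP of each gene list for the 12 list and mark combinations outside the 95% range of matched random lists (bars) in both hearts; circles are the normal and squares the failed heart. Developmental transcription factor genes lie below their range for H4ac (-0.93 and -1.25) and above it for K9me3 (1.10 and 0.76).

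The genes with the highest enrichment over both hearts were named for each mark. Ppp1r21 had H3ac enrichments of 3.73 in the normal and 4.04 in the failed heart, and Mif4gd 4.59 and 1.37. For H4ac, Nr2f6 had 2.49 and 3.38 and Heatr4 3.04 and 2.40, and for K4me2 Tbcc had 3.57 and 3.73. Dennd1a had K4me3 enrichments of 2.58 and 3.41, Muc4, a mucin, K9me2 enrichments of 3.64 and 3.08, and Plcb1 K27me2 enrichments of 2.14 and 3.36. For K9me3, Giot1, a zinc finger gene, had 2.79 and 3.41 and Prkca 2.75 and 3.16. The remaining genes in these places had a pre-IP value at the floor in at least 1 heart, so their enrichments there are lower bounds. They were Nova2 for H3ac, K4me2, K4me3 and K9me2, Erbb2 for H4ac and K27me2, Dmrtc1a for K4me3 and K9me2, Metrn for K4me2, Zfp263 for K9me3 and K20me3, Klrb1c for K20me3 and K27me2, and Cr2 for K20me3.

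The next comparison asked whether genes with more mRNA carried more of a mark. Acetylation over pre-IP was higher at genes with more mRNA: rho across 14217 genes was 0.163 in the normal and 0.136 in the failed heart for H3ac and 0.195 and 0.232 for H4ac. With genes in 10 groups by mRNA level, most of this rise lay between group 1, the lowest, and group 6. For H3ac, groups 1, 6 and 10 had medians of -0.31, 0.16 and 0.18 in the normal heart. In the failed heart these were -0.23, 0.17 and 0.13. For H4ac they were -0.33, 0.17 and 0.23 in the normal and -0.44, 0.17 and 0.14 in the failed heart. K9me3 gave rho of 0.097 and 0.064. The other marks over pre-IP were lower at genes with more mRNA or near 0: -0.233 and -0.174 for K9me2, -0.221 and -0.250 for K27me2, -0.190 and -0.216 for K20me3, -0.138 and -0.115 for K4me3, and -0.021 and 0.024 for K4me2. The pre-IP level itself rose with mRNA, with rho of 0.208 and 0.179. Without pre-IP all 8 marks were positive in the normal heart: 0.283 for H3ac, 0.297 for H4ac, 0.274 for K9me3, 0.153 for K4me2, 0.123 for K4me3, 0.0746 for K20me3, 0.0577 for K27me2 and 0.0024 for K9me2. The sign for K4me2, K4me3, K9me2, K20me3 and K27me2 therefore depended on the pre-IP correction, while H4ac and H3ac ranked highest either way in the normal heart. In the failed heart without pre-IP, H4ac ranked highest at 0.279 and K9me3, at 0.228, came before H3ac.

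**Figure D3:**
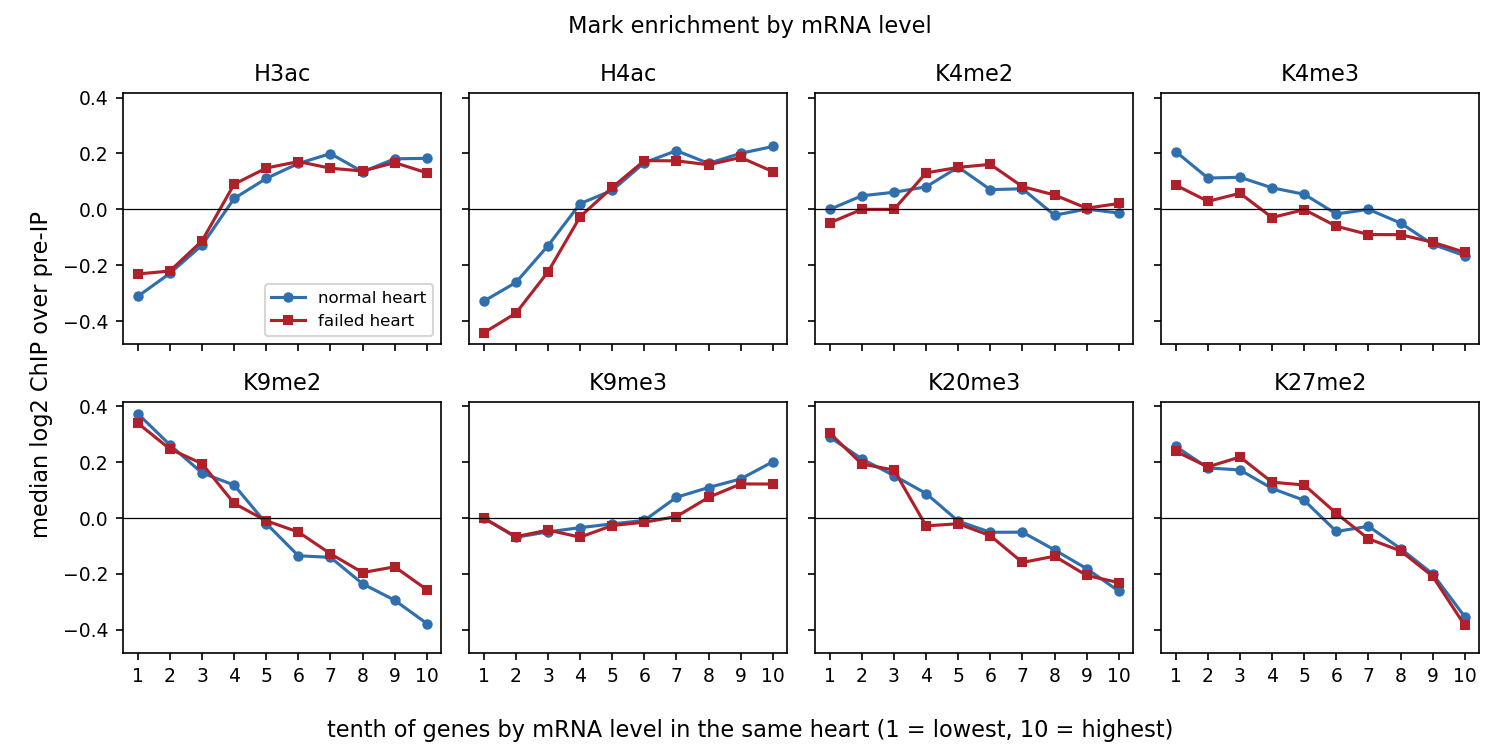
Median log2 ChIP over pre-IP for genes in 10 groups by mRNA level in the same heart, 1 panel per mark, with circles for the normal and squares for the failed heart. From the lowest to the highest group the normal heart goes from -0.33 to 0.23 for H4ac, with 0.17 already in group 6. For K9me2 it goes from 0.37 to -0.38. Without pre-IP, rho with mRNA for K9me2, K20me3, K27me2, K4me2 and K4me3 is positive.

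The comparison of marks between the hearts asked where a mark differed in the failed heart. The slow myosin gene Myh7 had less of several marks over pre-IP in the failed heart, where its mRNA was higher: it differed by -2.74 for H3ac, -2.79 for K4me2, -2.57 for K9me3, -1.65 for H4ac and -1.60 for K4me3. Its second probe set gave values between -0.57, for H3ac, and -1.11, for K4me2, for the same 5 marks. The fast myosin gene Myh6 had at least 4.68 more K27me2, its normal value being at the floor, but 0.40 at its second probe set. For H3ac Myh6 differed by 1.69, with -0.94 at the second probe set. Nppa differed by -1.25 for H3ac, -1.76 for H4ac, -1.21 for K4me2, -1.66 for K4me3, -1.97 for K9me2, -1.54 for K20me3 and -1.58 for K27me2, while its pre-IP value was higher by 1.34. Without pre-IP these became 0.09, -0.42, 0.13, -0.32, -0.63, -0.20 and -0.24. Nppb differed by -0.93 for H3ac and Acta1 by 1.54 for K9me3 and 1.46 for K20me3. Pdk4 differed by 1.78 for K4me2, Atp2a2 by 1.44 for K27me2, with a probe set at -0.76, and Col1a1 by 0.75 for K9me3. The other values at these 8 genes ranged in size up to 1.96.

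For each mark the largest differences were at these genes. H3ac was higher at Zc3h12a, a regulator of inflammatory mRNA, by 4.06, Ptafr by 3.44 and Kctd18 by 3.26, with -1.10 at another probe set of Kctd18, and lower at Acads at -3.55, Cdc37 at -3.36 and Slc4a3 at -3.26. H4ac was higher at Gngt1 by 2.79, Chrd by 2.54 and Tefm by 2.51, and lower at Acads at -3.72, Galr3 at -3.26 and Klhdc7a at -2.95. K4me2 was higher at Ttc32 by 2.96, Ddah2 by 2.94 and Rnf141 by 2.93, and lower at Acads at -3.41, Pgls at -3.35 and Myh7. K4me3 was higher at Rnf103 by 3.36, Tefm by 2.79 and Ndufb2 by 2.51, and lower at Gstt2 at -3.36, Abhd16a at -3.16 and Zcchc17 at -3.15. K9me2 was higher at Med31 by 4.86, with -0.12 at its other probe set, Cdh22 by 4.46 and Polr1c by 4.21, and lower at Galr3 at -4.82, Dock3 at -4.16 and Slc2a1 at -4.11. K9me3 was higher at Wfs1 by 4.04, C20h22orf15 by 3.48 and Acsf3 by 3.44, and lower at Gstt2 at -4.14, Rpp21 at -4.12 or lower and Cldn22 at -4.00 or lower, the last 2 with failed values at the floor. K20me3 was higher at Cdh22 by 4.42, Rap1gap2 by 3.55 and Tekt3 by 3.17, and lower at Med16 at -3.22, Xpo4 at -3.11 and Hhip at -3.10. K27me2 was higher at Armc6 by 3.16, Cul7 by 3.08 and Acsf3 by 2.86, and lower at Pcbd2 at -3.17, with 0.51 at its other probe set, Galr3 at -2.89 and Sbsn at -2.49. In 45 of these 48 places the pre-IP value differed in the opposite direction, as at Acads, where pre-IP was higher by 3.27. Without pre-IP 36 of the 48 were still past 2-fold in the same direction. The mRNA of the gene was past 2-fold in the same direction in 3 and in the opposite direction in 8.

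Counted over all genes compared, 753 had at least 2-fold more H3ac in the failed heart and 614 less, 19.3% of 7077. H4ac gave 344 and 456 (11.4%), K4me2 804 and 467 (18.1%), K4me3 629 and 698 (18.7%), K9me2 1112 and 649 (25.3%), K9me3 644 and 809 (20.5%), K20me3 632 and 606 (17.5%) and K27me2 481 and 449 (13.2%). The pre-IP arrays alone gave 275 and 248 (7.46% of 7015), with Dcaf8 at 2.48, Ttc9 at 2.44, Slco2a1 at -2.37 and Fkbp9 at -2.08 the farthest apart. The excess of higher genes for K4me2 turned to 477 higher and 787 lower as deposited, where the array medians differed by -0.21, and to 659 and 800 with quantile normalization. For K9me2 quantile normalization gave 891 higher and 850 lower and the values as deposited 909 and 787. Smaller excesses also turned: H3ac to 687 and 810 with quantile normalization, H4ac to 385 and 380 as deposited, K9me3 to 755 and 691 as deposited and 759 and 735 with quantile normalization, and K27me2 to 462 and 463 as deposited and 452 and 488 with quantile normalization. Without pre-IP, K4me3 turned to 191 and 149 and K20me3 to 317 and 336. K9me2 had 572 and 249 without pre-IP but 2356 and 2675 without the level filter, so none of the 8 marks is read as higher or lower over all genes. ChIP arrays compared without pre-IP gave fewer genes for every mark, from 340 for K4me3 to 836 for K9me3.

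Differences over pre-IP were weakly correlated between 2 probe sets of a gene. Among the 48 places above, 12 were at genes with another probe set: in 9 the direction was the same at each probe set, and in 3 it was opposite at 1 probe set. The sizes differed widely: beside -3.36 Gstt2 had -2.16 for K4me3 and beside 4.42 Cdh22 had 1.57 for K20me3, but Gstt2 had only -0.86 for K9me3 and Cdh22 0.50 for K9me2, and Xpo4 and Med16 had -0.23 and -0.32 for K20me3 and Rnf141 0.46 for K4me2. Pearson's r between the differences of 2 probe sets was 0.099 for H3ac, 0.059 for H4ac, 0.053 for K4me2, 0.10 for K4me3, 0.098 for K9me2, 0.049 for K9me3, 0.035 for K20me3 and 0.083 for K27me2, all under the 0.13 of pre-IP DNA and the 0.44 of mRNA. With ChIP arrays alone r was 0.24 for H3ac, 0.32 for H4ac, 0.21 for K4me2, 0.16 for K4me3, 0.10 for K9me2, 0.13 for K9me3, 0.089 for K20me3 and 0.16 for K27me2. For enrichment in the normal heart it lay between 0.20 for K4me3 and 0.39 for K27me2. Individual genes with a large mark difference over pre-IP are thus not separated from noise between single arrays here.

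**Figure D4:**
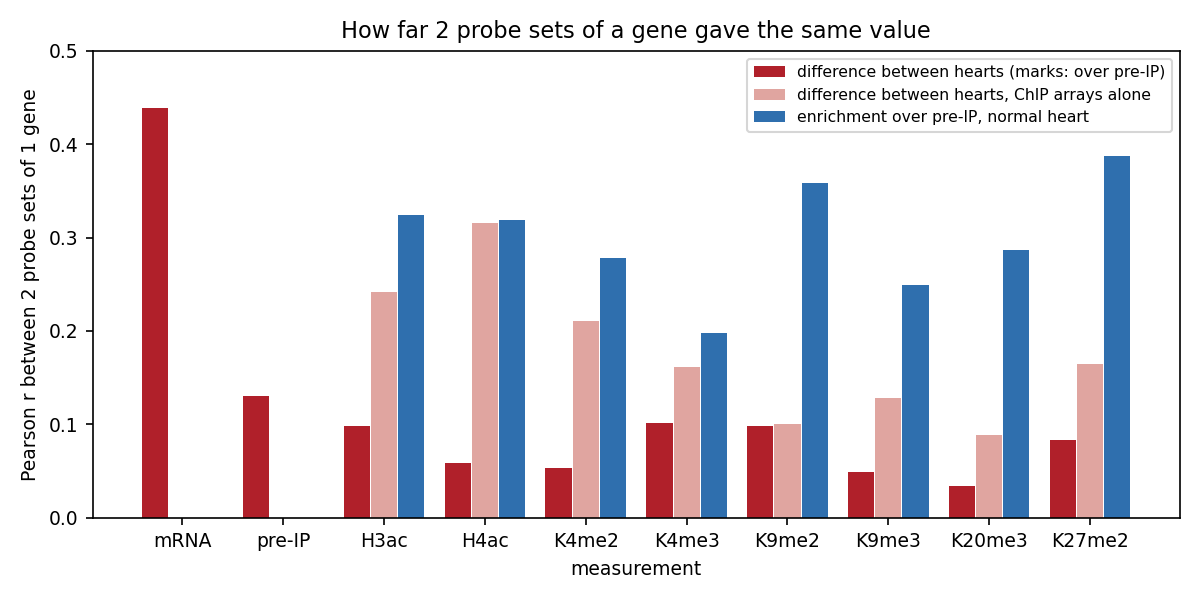
Pearson's r, across genes, between 2 probe sets of the same gene, for the difference between the hearts (dark red; marks over pre-IP), the difference on ChIP arrays alone (light red) and the enrichment in the normal heart (blue). For differences, mRNA reached 0.44 and pre-IP DNA 0.13, and the 8 marks over pre-IP stayed between 0.035 and 0.10.

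Over gene lists, 9 of 160 medians of mark differences lay outside their matched ranges, where 8 would be expected by chance, so no list is read as differing. Glycolysis genes had lower H3ac, with a median of -0.58, and K4me3, with -0.62, and respiratory chain genes lower H3ac, with -0.43. Hypertrophy genes had lower K4me2, with -0.41, and K4me3, with -0.64, adipocyte markers lower K4me2, with -0.84, which was 0.17 without pre-IP, and sarcomere genes higher K20me3, with 0.52, and K27me2, with 0.58. Extracellular matrix genes had higher H4ac, with 0.25. In at least 1 other setting 8 of these 9 lay inside the matched range, the exception being K4me3 of hypertrophy genes. Without pre-IP sarcomere K20me3 was 0.07, at percentile 68.6, sarcomere K27me2 0.31, at 94.7, and glycolysis K4me3 -0.17, at 25.2. With quantile normalization respiratory chain H3ac was -0.28, at percentile 12.2, and hypertrophy K4me2 lay at 5.98. Glycolysis H3ac lay at 2.57 when probe sets were averaged, and extracellular matrix H4ac was 0.16, at 97.3, with the floor at 50. The pre-IP difference itself lay outside for 4 of 20 lists, at -0.34 for fatty acid oxidation genes, -0.28 for respiratory chain genes, 0.43 for macrophage and leukocyte markers and 0.67 for adipocyte markers.

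Mark differences were then compared with mRNA differences, to ask whether genes with more mRNA in the failed heart also had more of a mark there. Across 9317 genes rho was -0.0053 for H3ac, 0.011 for H4ac, 0.019 for K4me2, 0.0045 for K4me3, -0.0082 for K9me2, 0.025 for K9me3, 0.022 for K20me3 and -0.026 for K27me2, beside -0.014 for pre-IP DNA. No relation was detectable at this noise. At the 1104 genes with 2-fold higher mRNA the median differences of the 8 marks lay between -0.09 for K4me3 and 0.06 for K4me2, and at the 293 genes with 2-fold lower mRNA between -0.11 for H4ac and 0.15 for K27me2. Of these 16 medians, K27me2 at genes with lower mRNA, at percentile 99.9, and K20me3 at genes with higher mRNA, with a median of 0.0048 at percentile 97.8, lay outside their matched ranges. The K4me2 median at genes with lower mRNA was 0.06, and -0.06 with quantile normalization.

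The differences of the 8 marks were also compared with each other. Over the 28 pairs rho had a median of 0.495. With each mark's ChIP differences shuffled across genes before the shared pre-IP difference was subtracted, the median was 0.493. Single pairs departed both ways: H3ac with K4me3 had 0.646 against 0.521 shuffled, and K4me2 with K9me3 0.372 against 0.459. Shuffling also breaks any relation of ChIP to pre-IP differences. The close medians therefore do not show that shared pre-IP accounts for all of the agreement. Without pre-IP the median was 0.109, with a range from -0.056 to 0.284.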

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

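Of the tests below, the one for RNA carried over into the DNA was completed only after part of its result was seen; its first form used sarcomere genes alone, and their values went with carry-over. The control probe sets of the array are in no comparison of the report, apart from the ratios of 3′ to 5′ signal for RNA, and several of them were bright on genomic DNA. The middle probe set of the GAPDH control, designed against an abundant mRNA, was 95.1 times the array median on the pre-IP genomic DNA array of the normal heart and 106.2 times on that of the failed heart. On the same arrays, in deposited units, the 3′ probe set of GAPDH had 21234 and 21322, the 5′ probe set 13555 and 12915 and the 5S ribosomal RNA control 11767 and 7029. On the mRNA arrays the middle probe set was 5.67 and 7.37 times the array median. Control probe sets for bacterial spikes, which match no rat sequence, had a median of 14.9 on the normal and 13.3 on the failed pre-IP array, where the array medians were 366 and 371. The middle GAPDH probe set was also at least 48.5 times the array median on every ChIP array. Control probe sets were not part of any gene count, list or rho in the report.

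A wider pattern was that pre-IP DNA signal rose with mRNA, with rho of 0.208 in the normal and 0.179 in the failed heart. Processed pseudogenes, DNA copies of abundant mRNAs, may add to it: 1384 genes with a named pseudogene lay at percentile 100 in pre-IP level among lists matched on mRNA level, in both hearts, and Gapdh has 81 named pseudogenes. Without these genes rho was still 0.183 and 0.155, so genes with a named pseudogene do not make up the whole relation. Copies without a name in the gene table would stay in, so processed pseudogenes at large are not excluded as its source. RNA carried over into the DNA stays open: sarcomere genes lay at percentiles 99.98 and 99.9 in pre-IP level among unmatched lists, but 327 abundant genes with 2-fold higher mRNA in the failed heart had a median pre-IP difference of -0.07, at percentile 82.1 of lists matched within abundant genes. Brightness of the probes themselves was not tested, and no biological explanation was tested.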

How the results depend on the processing

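The tests of gene lists and enrichments on the values as deposited and of enrichment over the mean of both pre-IP arrays were chosen only after the data were seen. No paired analysis was possible because each group had 1 array and the labels give no shared replicates; for the same reason no array was left out.

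The 32 mRNA differences of genes named by rule kept their sign under 5 other settings, where 69 values moved by more than 0.1 and 91 did not. The rho of mark differences with mRNA differences stayed near 0 in 48 of 48 tests. Counts past 2-fold changed by less than 1.5 times except in these settings. Without the level filter more genes were compared, and the counts were 3366 for mRNA, 2203 for pre-IP, 3929 for H3ac, 3008 for H4ac, 3850 for K4me2, 3753 for K4me3, 5031 for K9me2, 4113 for K9me3, 4010 for K20me3 and 3179 for K27me2. Without pre-IP, which takes out the noise of 2 arrays, they were 621 for H3ac, 379 for H4ac, 648 for K4me2, 340 for K4me3, 821 for K9me2, 836 for K9me3, 653 for K20me3 and 370 for K27me2. Low signal limits these counts: among the 3555 genes with the lowest mRNA level 45.7% were past 2-fold, against 18.3% among the 3554 with the highest.

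The rho of enrichment with mRNA in the normal heart moved by more than 0.1 without pre-IP: to 0.283 for H3ac, 0.297 for H4ac and 0.274 for K9me3, and to the other sign at 0.153 for K4me2, 0.123 for K4me3, 0.0024 for K9me2, 0.0746 for K20me3 and 0.0577 for K27me2. The pre-IP level itself follows mRNA, so subtracting it lowers these values by construction. Over the mean of both pre-IP arrays it moved by less than 0.1 for each mark. The median rho between marks was 0.109 without pre-IP, which the marks share.

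Among mRNA list medians, hypertrophy genes had 1.23 with quantile normalization, 1.43 with the mean of probe sets and 1.34 as deposited. Extracellular matrix genes had 0.80 with quantile normalization and 0.85 as deposited, and respiratory chain genes 0.35 and 0.57. Glycolysis genes had 0.52 and 0.64 and ribosomal protein genes 0.26 and 0.61. Fatty acid oxidation genes turned to -0.060 and -0.018 in these settings. As deposited, the shift of -0.27 between the mRNA array medians stays in every gene away from the floor. For quantile normalization and the mean of probe sets the cause was not tested. The endothelial median turned to 0.14 with the mean of probe sets.

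For marks, the K4me2 median at genes with lower mRNA turned to -0.057 with quantile normalization, and that of adipocyte markers to 0.046 with a floor of 50 and 0.17 without pre-IP. The cause was not tested. At named genes, 246 values of a mark moved by more than 0.1 and 416 did not. Of those past 2-fold, 4 more took the other sign, each without pre-IP: Nppa at 0.086 for H3ac and 0.13 for K4me2, Pgls at 0.21 for K4me2 and Pcbd2 at 0.18 for K27me2. In these 4 the pre-IP arrays differed by more than the ChIP arrays. Values under 2-fold changed sign in several settings, such as Nppa for K9me3, at 0.69 without pre-IP. Of the list differences, only the 9 that lay outside the matched range were followed in each setting. The enrichment medians of the 12 list and mark combinations kept their sign in 72 tests, except for a value of 0.00 with a floor of 50, and 30 moved by more than 0.1.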

Other observations

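The zinc finger genes and the genes with pseudogenes were chosen as groups after their values were seen, and the tests of noise in the mark differences and of zinc finger genes under other settings were chosen only after the results were seen. Genes of the zinc finger family (229 named Zfp or Znf with a number) were high in K9me3, a mark of silent chromatin, in both hearts. Their median K9me3 enrichment was 0.44 in the normal and 0.45 in the failed heart, above all matched lists, and 156 and 151 of them lay above 0. For K20me3 they had 0.23 and 0.25, at percentiles 94.4 and 99.8. They were low in acetylation, at -0.34 and -0.40 for H3ac and -0.16 and -0.38 for H4ac, but with the floor at 50 these 4 medians were 0.00, at percentiles between 46.9 and 48.5. With that floor the K9me3 medians were 0.19 and 0.23, still above all matched lists, and those for K20me3 0.048 and 0.047. With quantile normalization and as deposited the medians of these 4 marks kept their sign, but sizes moved. The failed heart's H3ac median was -0.16 with quantile normalization and -0.77 as deposited, and the normal heart's H4ac median -0.07 and -0.43. The normal heart's K9me3 median moved less, to 0.44 and 0.51.

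For probe sets shared between related copies and bright on every array, the prediction set was that acetylation would be high as well. The highest of the 4 percentiles for H3ac and H4ac was 0.19, or 48.5 with the floor at 50. Brightness shared with the pre-IP array cancels in enrichment, so these percentiles cannot decide on that explanation. If a low pre-IP value raised every enrichment, K9me3 minus K27me2, in which pre-IP cancels, would lie within the matched range, and it had medians of 0.45 and 0.54, at percentile 100 in both hearts. Without probe sets named for shared sequence, the K9me3 medians were 0.43 and 0.44, and those for K20me3 0.19, at percentile 84.2, and 0.23, at percentile 99.6. Genes with named pseudogenes also had K9me3 above all matched lists in both hearts, with medians of 0.16 in the normal and 0.06 in the failed heart. Signal from other genomic copies that carry the mark may therefore contribute and was not tested. The sequence of the probes, and with it GC content, was not used here.

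The near absence of a relation between mark differences and mRNA differences was weighed next. Differences over pre-IP between single arrays may be mostly noise, since in 8 of 8 marks the differences of 2 probe sets of a gene correlated no better than those of pre-IP DNA. Different chromatin at the places of 2 probe sets stays open. Enrichment itself correlated above 0.2 between them in 7 of 8 marks, so part of it was shared. The highest value in the normal heart was 0.39, for K27me2, and probe positions were not used, so the test cannot decide. Without pre-IP the lower of the H3ac and H4ac values was 0.24, against 0.13 for pre-IP DNA. H3ac and H4ac had the highest values of the 8 marks, so part of their differences recurred between probe sets. A bias of a single array that the probe sets of a gene share would recur as well. The values therefore cannot decide on noise of single ChIP arrays. A difference between the 2 animals or preparations stays open beside heart failure, because each heart was measured once.

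A hypothesis was that a mark spreads over domains wider than a gene, so that neighbours on a chromosome share it. Over 13370 pairs of adjacent genes with unlike symbols, rho of the mean enrichment of both hearts was 0.318 for H3ac, 0.283 for H4ac, 0.204 for K4me2, 0.190 for K9me2, 0.165 for K20me3, 0.147 for K27me2 and 0.060 for K4me3, where 100 shuffles of gene order gave at most 0.028. For K9me3, for which the test was set, rho was 0.085, between the bounds of 0.05 and 0.1 set for the answer, so it may or may not form such domains here. With each gene taken from one heart and its neighbour from the other, rho was lower for each mark: 0.244 for H3ac, 0.217 for H4ac, 0.150 for K4me2, 0.141 for K9me2, 0.108 for K20me3, 0.111 for K27me2, 0.055 for K9me3 and 0.023 for K4me3. The value for K4me3 lay under the highest of the shuffles over all marks but above the highest for K4me3 itself, 0.015. Differences between the hearts had rho of at most 0.032 between neighbours. Shuffling also breaks up any regional signal unrelated to a mark, which was not tested, and no pre-IP value stands beside these. The values above the shuffles thus cannot by themselves be read as chromatin domains.

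The arrays themselves gave further values. The pre-IP arrays of the hearts correlated with rho of 0.839. In the normal heart, 4 of 8 ChIP arrays (H3ac, H4ac, K4me2 and K4me3) were closer to the pre-IP array of the failed heart than to their own, and in the failed heart 1, K9me2, was closer to that of the normal heart.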
